A study of Mus musculus with 18 samples.

How the data were processed

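RNA sequencing counts of 18 libraries from sorted mouse cells were used: DP (n = 3), iRTE (n = 5), OP9 CD8 (n = 5) and splenic naive CD8+ cells (n = 5). Per the labels, cells were sorted on CD45, CD4, CD8 and the alpha-beta T-cell receptor, with NK1.1, the gamma-delta receptor and CD11c in a dump gate. The labels do not say that replicates came from separate cultures or animals, so p-values measure only the spread between these samples.

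The count values were deposited as whole numbers per gene symbol, which the authors made, per the submitters' processing notes, by aligning reads with STAR 2.4.2 to build mm9 and counting with Subread. The deposited file headers name a sorted alignment with read groups and duplicate marking. The annotation release and the strand setting are not given in the sources used here. A second table holds log2 values, which the authors made with edgeR per the submitters' processing notes, for 17765 of the 43280 genes. Tested on the files, these log2 values equal TMM-normalised log2 CPM with a prior count of 2, and the table served only for that check. Every column of it was matched to a library, and no sequence or coordinate was used.

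Total counts per library ran from about 11132800 to 19305800. At these depths 3 counts equal 0.155 to 0.269 CPM, the floor used per library for genes with no count in a group: folds against such groups are given as "at least", from the mean of the other group. These floors cover counting error only, not the spread between cultures. No fold is given where both groups lie at or under the floor. Replicates differed by more than counting error, with a chi-square per degree of freedom of at least 4.66 over pairs of replicates.

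Genes were kept by the default filter of edgeR 4.0.16 in R 4.3.3 (13922 genes), and libraries were scaled by TMM. All 18 libraries entered a quasi-likelihood fit with a coefficient per group and robust dispersions. The 6 comparisons were tested by edgeR quasi-likelihood F tests, with Benjamini-Hochberg adjustment over the genes and a threshold of 0.05. A gene counted as not overlapping when every library of a group lay above every library of the other. SE values use within-group variances of log2 CPM with a prior count of 2, not the fit.

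Of 30 gene lists written by hand, 27 with at least 5 measured members were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. The lists covered naive and quiescence, DP thymocyte, positive selection, cytotoxic effector, innate receptor, inhibitory receptor, cell cycle, glycolysis, hypoxia, oxidative phosphorylation, cholesterol synthesis, interferon response, MHC class I, T-cell receptor signalling, trafficking, endoplasmic reticulum and amino acid stress, immediate early, p53 and apoptosis, fetal programme, imprinted, stromal, thymic epithelial, B-cell, myeloid, erythroid, gamma-delta T and CD4 helper genes. Lists of pluripotency (1 measured member) and mast cell genes (3 measured members) were too short to test, and sex-linked genes served as a check. Counts "adjusted over the list alone" adjust the same p-values over the members of that list.

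The distance of a library to splenic cells was the root mean square difference of log2 CPM from the splenic mean, and its position was the projection on the line from the DP mean to the splenic mean. Genes for the position were chosen from the DP and splenic libraries, at an adjusted p under 0.05 and a change of at least 2-fold. Groups were compared by exact two-sided permutation of the library labels. The overlap of the 2 comparisons with splenic cells was set beside 20 simulations without change and 20 divisions of the splenic libraries.

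Genes were named by a rule. It took (a) the 6 largest rises and falls (3 in the last 2 comparisons) among genes past the threshold, with no overlap and a mean of at least 10 CPM in the higher group, leaving out predicted and clone-named genes. It took (b) for each list described the 2 called members with the smallest adjusted p in the list's main direction, 1 in the other, and up to 2 not passed, and (c) key genes of T-cell development. Some genes that this rule names are not reported here. Groups, comparisons, tests, the lists, this rule and the alternatives named first below were fixed before the data were examined.

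The pipeline was tested on data simulated from these libraries, with 200 of 13922 genes changed 2-fold or 4-fold per comparison. It recovered 70% of 2-fold and 94% of 4-fold changes for iRTE against OP9 CD8 (5.75% of calls false). Against splenic cells it recovered 69% and 87% for iRTE (2.5%) and 62% and 84% for OP9 CD8 (7.01%). Against DP it recovered 53% and 86% for iRTE (4.79%), 55% and 84% for OP9 CD8 (7.95%) and 48% and 88% for splenic cells (4.9%). The data gave 2041 to 8435 calls, so these rates hold only for the simulation. Simulated positions were off by at most 0.00239.

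Replicate numbers are shared between groups. Over 24 pairs of libraries with the same number, residuals correlated at r = -0.0663 to 0.0587, so the numbers were not taken as pairs, and a fit with the number as a replicate block was tried as an alternative. The other alternatives chosen at that time were RLE and upper quartile scaling, no filter, a filter of 10 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit of only the 2 groups compared, a label set term, a 2-fold threshold and leaving out each library in turn. Lists were also tested with an estimated correlation and with fry, and the distance as 1 minus Spearman correlation. Neither scaling alternative moved the median of all genes by over 0.1 on the log2 scale. Chosen after seeing the data were iRTE 1 to 3 or iRTE 4 and 5 alone (except for the planned distance and position of iRTE 4 and 5), lists without iRTE 5 or DP 1, the distance without some lists, and limma-voom with library weights. Nothing was left out of the 18 libraries. Values of genes in multigene families (H2, Ifit, Ifitm, Ly6, Ms4a, Oas, Slfn and others) are uncertain, since reads can be shared, and the text notes this for only some.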

Results

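RNA was sequenced from 18 libraries of sorted mouse T-lineage cells in 4 groups. DP cells (n = 3) were CD4+CD8+ cells grown from induced pluripotent stem cells, named Pmel iPSC in the labels, on OP9-DL1, a stromal line carrying a Notch ligand that drives T-cell development in a dish. OP9 CD8 cells (n = 5) were CD8+ cells made on OP9-DL1 from the same source. The iRTE cells (n = 5) were CD8+ cells of that source too. The labels do not spell out the abbreviation. By elimination iRTE is the group that the design text places in a 3D thymic culture, although each iRTE sample's growth protocol names OP9-DL1. The reference group was naive CD8+ cells from the spleen of transgenic mice (n = 5).

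Total counts per library ran from about 11747400 to 12208200 in DP, 11691300 to 16533400 in iRTE, 15953400 to 19305800 in OP9 CD8 and 11132800 to 17671900 in splenic cells. The iRTE libraries spread most, with a median gene log2 SD of 0.316 (0.209 in DP, 0.121 in OP9 CD8 and 0.105 in splenic cells). Spearman correlations between replicates, taken across genes, ran from 0.935 to 0.984 in iRTE and from 0.991 to 0.994 in splenic cells. The first principal component held 47.0% of the variance and the second 18.9%. By their descriptions, libraries were assigned to set A (DP, iRTE 1 to 3) or B (the other 10), which may mark a batch. Description styles differ within both sets, so the sets are a guess. Only iRTE spans both sets, so DP could be compared within a set with iRTE 1 to 3 alone, and OP9 CD8 and splenic cells with iRTE 4 and 5 alone. Fold changes are fitted log2 values of the first group relative to the second, with ± SE of log2 CPM, not of the fit. CPM are group means ± SD over the libraries above.

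The first comparison asked how iRTE cells, which the labels place in the 3D culture only by elimination, differed from the OP9 CD8 cells. Rag1, needed to rearrange receptor genes, averaged 0.632 ± 1.36 CPM in iRTE and 153 ± 12.6 CPM in OP9 CD8 cells, a log2 change of -7.70 ± 0.89. Rag2 changed by -6.98 ± 0.74, Dntt, which adds bases at receptor joints, by -3.62 ± 0.64, and Cd24a, a surface marker lost on maturation, by -4.70 ± 0.76. Cd4 had no count in any iRTE library and averaged 4.41 ± 2.85 CPM in OP9 CD8 cells, at least 18.4-fold lower against a floor of 3 counts per library. Adjusted p for these genes lay between 4.58e-09 (Rag2) and 4e-06 (Cd4) in the edgeR quasi-likelihood F test with Benjamini-Hochberg adjustment. Single libraries set the size of some of these values: the change was -12.36 for Rag1 and -7.90 for Rag2 without iRTE 5, and -4.38 for Dntt and -5.43 for Cd24a without iRTE 4.

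Cd8b1 averaged 2546 ± 498 CPM in iRTE and 920 ± 91.3 CPM in OP9 CD8 cells (1.47 ± 0.14), and Cd8a rose by 0.99 ± 0.31 although iRTE 4, at 456 CPM, lay below every OP9 CD8 library. The lymph node homing receptor Ccr7 rose by 0.80 ± 0.16, Il7r by 1.07 ± 0.27, the egress receptor S1pr1 by 0.96 ± 0.25, Klf2 by 0.75 ± 0.27 and the chemokine receptor Ccr9 by 1.34 ± 0.12. The early activation marker Cd69 rose by 4.07 ± 0.96, by 1.83 without iRTE 5, which held 1287 CPM. The inhibitory receptor Pdcd1 fell from 166 ± 10.5 to 3.58 ± 2.16 CPM. Eomes fell by 1.73 ± 0.54, Il2rb by 0.85 ± 0.23 and Tbx21 by 1.89 ± 1.14, and the call of Tbx21 was lost without OP9 CD8 4 (-1.76) or in a fit of these groups alone (-1.91). Gzmb did not pass (1.13 ± 0.89, edgeR adjusted p = 0.0588), but rose by 1.44 without iRTE 4, the library with 6.85 CPM. The proliferation marker Mki67 did not pass either (-0.91 ± 0.74, edgeR adjusted p = 0.121), but fell by 1.66 without iRTE 5, by 1.56 with limma-voom and by 1.23 with a replicate block. Cd44 stood near 2.2 CPM in both groups (0.00 ± 1.00) and fell with iRTE 4 and 5 as the only iRTE libraries (-3.70).

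The largest rises with no overlap between the groups were Fgl2 (221 ± 135 against 3.07 ± 1.01 CPM, 6.16 ± 0.60), Rgs1 (6.14 ± 0.87), BC064078 (6.01 ± 0.93), Klhl14 (5.73 ± 0.86), Fam135b (5.51 ± 0.90) and Osgin1 (5.19 ± 0.87). Esm1 was at least 63.2-fold, Ldoc1l at least 62.6-fold, Rtp1 at least 57.5-fold and Evc at least 56.9-fold lower, all with no count in iRTE, and Tmem151b changed by -8.73 ± 0.13. OP9 CD8 libraries with few counts set some of these sizes: BC064078 rose by 7.83 without OP9 CD8 5, and Klhl14 by 6.34 and Fam135b by 6.41 without OP9 CD8 4. Tmem151b changed by -10.20 without iRTE 5.

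Of 13922 genes tested, 2788 were higher and 2598 lower in iRTE, of which 934 and 1443 changed at least 2-fold. The groups did not overlap at 3280 genes (23.6%, where chance gives 0.794%). Within set B, iRTE 4 and 5 were higher than OP9 CD8 cells at 2447 genes and lower at 2249, and iRTE 1 to 3 were higher at 2786 and lower at 2835.

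**Figure D1:**
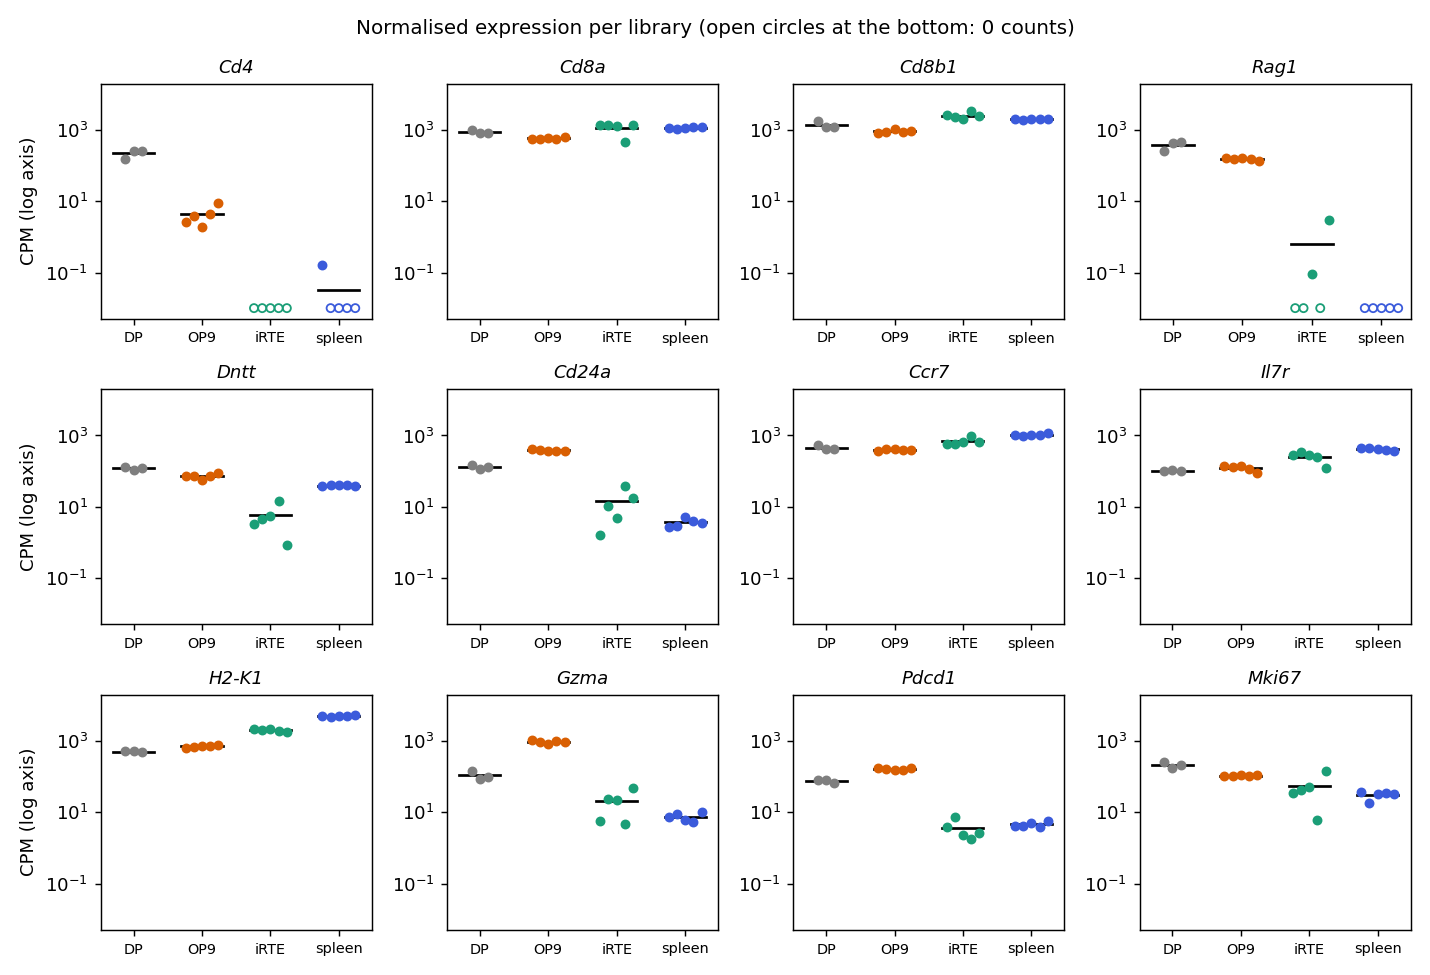
Normalised CPM of 12 genes in each library on a log axis, with a point per library, a bar at each group's mean and open circles for libraries with no count. Rag1 averaged 153 CPM in OP9 CD8 and 0.632 CPM in iRTE libraries, and H2-K1 stood at 707 CPM in OP9 CD8, 2009 CPM in iRTE and 4995 CPM in splenic cells.

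Among the gene lists, those of antigen presentation and the interferon response were higher in iRTE. In the interferon response list 33 of 40 genes rose and 7 did not pass (34 rose adjusted over the list alone), with Usp18 up by 2.32 ± 0.26 and Oasl2 by 2.61 ± 0.28. The camera adjusted p was 1.33e-14, with adjusted p = 0.0896 with an estimated correlation. In the MHC class I list 18 of 21 genes rose and 1 fell (18 and 1 adjusted over the list alone), with H2-D1 up by 1.72 ± 0.09 and H2-K1 by 1.51 ± 0.08 (camera adjusted p = 9.85e-13, adjusted p = 0.0896 with an estimated correlation). Both lists were also higher in iRTE 4 and 5 alone, with 26 and 13 genes up. Of 26 naive and quiescence genes 17 rose, Slfn2 by 1.93 ± 0.13 and Ms4a4b by 1.35 ± 0.10, and 4 fell, among them Tcf7 by 0.46 ± 0.09 (18 and 4 adjusted over the list alone, camera adjusted p = 1.44e-06, adjusted p = 0.0896 with an estimated correlation). Of 28 T-cell receptor signalling genes 17 rose and 5 fell (18 and 5 adjusted over the list alone, camera adjusted p = 0.0152, adjusted p = 0.0896 with an estimated correlation), a call lost in iRTE 4 and 5 alone. Of 23 trafficking genes 11 rose, Cxcr6 by 3.64 ± 0.16, and 3 fell, Cxcr5 by 3.86 ± 0.42 (11 and 4 adjusted over the list alone, camera adjusted p = 0.0115, adjusted p = 0.0896 with an estimated correlation). The test and the median of this list (0.29) were positive and its mean (-0.14) negative. Of 20 immediate early genes 11 rose, Jun by 4.48 ± 0.32 and Klf6 by 1.38 ± 0.14 (13 adjusted over the list alone, camera adjusted p = 0.000655, adjusted p = 0.348 with an estimated correlation). Their median of 1.25 fell to 0.52 without iRTE 5, where 9 rose and 4 fell of 19 members.

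Other lists fell in iRTE. In the DP thymocyte list 20 of 26 genes fell and 4 rose (20 and 4 adjusted over the list alone, camera adjusted p = 6.42e-11), the only list of this comparison whose call held with an estimated correlation (adjusted p = 0.000161). Of 44 cell cycle genes 38 fell, Mcm5 by 1.51 ± 0.27 and Rrm1 by 1.68 ± 0.39, and 6 did not pass (39 fell adjusted over the list alone, camera adjusted p = 4.26e-12, adjusted p = 0.3 with an estimated correlation). Their median was -1.02 in iRTE 1 to 3 and -1.54 in iRTE 4 and 5, where iRTE 4 stood apart with a list mean of 4.19 (other iRTE 6.07 to 6.31). Of 26 endoplasmic reticulum and amino acid stress genes 16 fell, Asns by 4.04 ± 0.43 and Slc7a5 by 1.78 ± 0.12, and 2 rose, Xbp1 by 0.57 ± 0.18 (16 and 2 adjusted over the list alone, camera adjusted p = 5.23e-06, adjusted p = 0.126 with an estimated correlation). Of 12 fetal programme genes 6 fell, Sox4 by 3.34 ± 0.53 and Hmga1 by 1.52 ± 0.16 (6 adjusted over the list alone, camera adjusted p = 5.61e-05, adjusted p = 0.126 with an estimated correlation). Of 25 cholesterol synthesis genes 12 fell and 2 rose, with a median of -0.55 (-0.48 with genes at their bound, 14 and 2 adjusted over the list alone, camera adjusted p = 0.0328, adjusted p = 0.691 with an estimated correlation). That call was lost in iRTE 1 to 3 alone and kept in iRTE 4 and 5, where iRTE 4 stood apart (list mean 4.29, other iRTE 5.48 to 5.90). Of 9 CD4 helper and regulatory genes 5 fell, Foxp3 by 4.04 ± 0.51 and Gata3 by 0.89 ± 0.08, and 2 rose (5 and 3 adjusted over the list alone, camera adjusted p = 0.0188, adjusted p = 0.0896 with an estimated correlation). Of 12 gamma-delta T genes 5 fell and 4 rose (5 and 4 adjusted over the list alone, camera adjusted p = 0.0229, adjusted p = 0.0896 with an estimated correlation), with a median of 0.15 and a mean of -1.36. The gamma-delta call was lost both in iRTE 1 to 3 and in iRTE 4 and 5 alone, and the CD4 helper call in iRTE 1 to 3 alone.

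The other 14 lists were not called by camera. Rose and fell counts, then the same counts adjusted over the list alone, were 8 and 7, then 10 and 7, of 28 cytotoxic effector genes (Ctsw rose by 2.17 ± 0.27 and S100a4 by 2.79 ± 0.33, and Gzma fell from 948 ± 69.9 to 20.6 ± 17.1 CPM). They were 10 and 7, then 11 and 7, of 23 positive selection genes, 7 and 5 both times of 21 innate receptor genes, 5 and 5 both times of 16 inhibitory receptor genes, and 6 and 12, then 7 and 14, of 24 p53 and apoptosis genes. Metabolic lists gave 6 and 5 both times of 22 glycolysis genes, 6 and 4 both times of 18 hypoxia genes and 7 and 1, then 6 and 1, of 36 oxidative phosphorylation genes. Lists of other cells and programmes gave 3 and 1 of 11 imprinted genes, 1 and 3 of 14 stromal genes, 1 and 3 of 6 thymic epithelial genes, 2 and 4 of 16 B-cell genes and 2 and 1 of 9 myeloid genes, the same adjusted over the list alone, and 1 and 1, then 1 and 0, of 8 erythroid genes. Camera adjusted p of these lists ran from 0.0565 (p53 and apoptosis) to 0.917. Medians and camera directions differed in sign for positive selection (0.33, lower by camera), innate receptors (0.14), inhibitory receptors (0.32), hypoxia (0.02), imprinted genes (0.11) and erythroid genes (-0.24, or 0.40 with such genes at their bound), and median and mean for cytotoxic effectors (0.41 and -0.07). With iRTE 4 and 5 alone the p53 and apoptosis list was called lower, and with iRTE 1 to 3 alone the oxidative phosphorylation list was called higher. Regrouping the same 10 libraries at random also gave list calls, at most 12 where the fit of these groups alone gave 15.

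The second comparison asked how far iRTE cells differed from naive CD8+ cells of the spleen. Cd8a stood at 1159 ± 395 CPM in iRTE and 1156 ± 53.4 CPM in splenic cells (0.00 ± 0.31, edgeR adjusted p = 0.993), and was higher in iRTE by 0.21 without iRTE 4. Cd8b1 rose by 0.34 ± 0.13, a call lost without iRTE 1 (0.32) or iRTE 4 (0.23) and in iRTE 1 to 3 alone (0.20). S1pr1 rose by 0.82 ± 0.24 and Klf2 by 0.73 ± 0.26, while Il7r fell by 0.70 ± 0.25 and Ccr7 by 0.59 ± 0.16 (edgeR adjusted p = 0.00108). The fall of Ccr7 was not past the threshold in iRTE 4 and 5 alone (-0.32). Ccr9 missed the threshold (-0.24 ± 0.12, edgeR adjusted p = 0.0523) and fell without iRTE 4 (-0.32) or iRTE 5 (-0.31) and with RLE scaling, the 10 CPM filter, DESeq2 or limma-voom. Rag1 was at least 3.09-fold higher in iRTE, where iRTE 5 held 3.07 CPM, and was not called without that library (1.76). Rag2 rose by 3.74 ± 0.76 from 0.0216 ± 0.0483 to 0.393 ± 0.562 CPM, by 2.82 without iRTE 5 and by 5.76 without splenic library 1. Limma-voom called neither Rag1 nor Rag2, and Rag2 turned in iRTE 1 to 3 alone (-2.04, not called). Dntt fell by 2.74 ± 0.64 (by 3.51 without iRTE 4), Cd24a rose by 2.01 ± 0.78 (by 1.28 without iRTE 4, and not called in iRTE 1 to 3 alone, 0.65) and Il2rb fell by 0.89 ± 0.23. Cd4 was at or under the floor in both groups.

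Gzmb rose from 2.36 ± 0.317 to 114 ± 78.5 CPM. Cd69, Cd44, Tbx21, Eomes, Pdcd1 and Mki67 did not pass, and single libraries or sets decided most of these. Cd69 changed by 0.32 ± 0.96 with all libraries and fell without iRTE 5 (-1.92). Tbx21 rose by 1.07 and Eomes by 0.94 without iRTE 5, Pdcd1 fell by 0.79 without iRTE 2 and Mki67 rose by 1.15 without iRTE 4. With iRTE 4 and 5 alone, Cd44 (-3.70), Tbx21 (-2.35) and Pdcd1 (-1.02) fell, and with iRTE 1 to 3 alone Tbx21 (1.43) and Eomes (1.05) rose.

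The largest rise was that of Nov, at 713 ± 482 CPM and at least 3492-fold higher than in splenic cells, which had no count. Next came the Y-linked Eif2s3y and Uty, at least 387-fold and 213-fold higher, Igf2, at least 201-fold higher, Ifitm1 (12.37 ± 0.79) and Ifitm2 (11.61 ± 0.55). Igf2 rested in part on iRTE 5, at 176 CPM, and its fitted change fell from 12.24 to 9.71 without it. Reads can be shared within the Ifitm family, so which member rose is uncertain, and without splenic library 5 the changes were 17.21 for Ifitm1 and 13.50 for Ifitm2. Tdgf1 was at least 80.6-fold, Ldoc1l at least 76.5-fold and As3mt at least 69.6-fold lower, and Xlr3b, a member of a multigene family, at least 143-fold lower. Xist, made from the inactive X chromosome, averaged 96.6 ± 16.9 CPM in splenic cells and 0.0374 ± 0.0836 CPM in iRTE (-10.79 ± 0.27, or -13.46 without iRTE 4). The beta globin Hbb-bt was at least 61.1-fold lower.

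Of the 13922 genes 4069 were higher and 4031 lower in iRTE, of which 2106 and 2454 changed at least 2-fold. There was no overlap at 5742 genes (41.2%, chance 0.794%). Within set B, iRTE 4 and 5 were higher at 3184 genes and lower at 2965, and iRTE 1 to 3 were higher at 4070 and lower at 4280.

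Growth and metabolic lists were higher in iRTE than in splenic cells. Of 44 cell cycle genes 43 rose, E2f1 by 2.54 ± 0.24 and Mcm2 by 1.53 ± 0.20 (43 adjusted over the list alone, camera adjusted p = 8.06e-14, adjusted p = 0.227 with an estimated correlation), with a median of 2.11 in iRTE 1 to 3 and 1.63 in iRTE 4 and 5. Of 36 oxidative phosphorylation genes 34 rose, Atp5a1 by 1.02 ± 0.10 and Ndufa9 by 1.53 ± 0.17 (34 adjusted over the list alone, camera adjusted p = 1.43e-11, adjusted p = 0.219 with an estimated correlation). Of 22 glycolysis genes 14 rose, Eno1 by 1.80 ± 0.12 and Pkm by 1.83 ± 0.15, and 3 fell (14 and 3 adjusted over the list alone, camera adjusted p = 1.01e-05, adjusted p = 0.0364 with an estimated correlation). Of 18 hypoxia genes 11 rose and 3 fell (11 and 3 adjusted over the list alone, camera adjusted p = 0.00908, adjusted p = 0.0399 with an estimated correlation). Of 25 cholesterol synthesis genes 19 rose and 1 fell (20 and 1 adjusted over the list alone, camera adjusted p = 3.67e-05, adjusted p = 0.279 with an estimated correlation). Of 26 endoplasmic reticulum and amino acid stress genes 19 rose, Sdf2l1 by 2.50 ± 0.22 and Xbp1 by 2.04 ± 0.18, and Ddit3 fell by 1.04 ± 0.30 (21 and 1 adjusted over the list alone, camera adjusted p = 7.84e-07, adjusted p = 0.118 with an estimated correlation). The fall of Ddit3 was not called in iRTE 4 and 5 alone (-0.65).

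Effector and lineage lists were also higher. Of 28 cytotoxic effector genes 16 rose, S100a4 by 9.93 ± 0.38 and Lgals3 by 8.33 ± 0.47 (9.04 without splenic library 5), and 3 fell, Prf1 by 2.78 ± 0.37 (16 and 4 adjusted over the list alone, camera adjusted p = 5.84e-06, adjusted p = 0.0705 with an estimated correlation). Of 21 innate receptor genes 11 rose and 2 fell (11 and 2 adjusted over the list alone, camera adjusted p = 0.0203, adjusted p = 0.224 with an estimated correlation). Of 16 inhibitory receptor genes 8 rose, Ctla4 by 5.54 ± 0.13 and Il2ra by 4.53 ± 0.60, and 3 fell (9 and 3 adjusted over the list alone, camera adjusted p = 0.00908, adjusted p = 0.219 with an estimated correlation). Of 24 p53 and apoptosis genes 12 rose and 7 fell (13 and 7 adjusted over the list alone, camera adjusted p = 0.0208, adjusted p = 0.0698 with an estimated correlation). Of 12 fetal programme genes 8 rose and 1 fell, with a median of 2.37 (1.67 with such genes at their bound, 8 and 1 adjusted over the list alone, camera adjusted p = 0.0146, adjusted p = 0.341 with an estimated correlation). Of 12 gamma-delta T genes 7 rose and 3 fell (7 and 3 adjusted over the list alone, camera adjusted p = 1.18e-08, adjusted p = 0.000451 with an estimated correlation). Among them the constant gene Tcrg-C2 rose from 30.8 ± 1.19 to 1227 ± 247 CPM and Cd163l1, of a multigene family, from 105 ± 5.93 to 3601 ± 948 CPM. Of 9 CD4 helper and regulatory genes 5 rose and 1 fell, with a median of 1.12 (2.18 with such genes at their bound, 5 and 1 adjusted over the list alone, camera adjusted p = 0.000588, adjusted p = 0.0238 with an estimated correlation). Within set B the innate receptor list was not called and its median was 0.38 (1.74 with all libraries), and that of the inhibitory list was 0.25 (1.55 with all libraries). The fetal programme call was lost in iRTE 1 to 3 alone.

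Interferon response, antigen presentation and receptor signalling were lower in iRTE than in splenic cells. Of 40 interferon response genes 25 fell, Usp18 by 2.16 ± 0.22 and Samd9l by 2.34 ± 0.16, and 5 rose, Ly6e by 1.13 ± 0.16 (25 and 5 adjusted over the list alone, camera adjusted p = 0.00169, adjusted p = 0.341 with an estimated correlation). Of 21 MHC class I genes 13 fell, Nlrc5 by 2.13 ± 0.16 and H2-K1 by 1.31 ± 0.07, and 5 rose, Psmb10 by 1.04 ± 0.19 (13 and 5 adjusted over the list alone, camera adjusted p = 0.00337, adjusted p = 0.338 with an estimated correlation). Both lists were called within set B and not in iRTE 1 to 3 alone. Of 28 T-cell receptor signalling genes 12 fell and 6 rose (12 and 6 adjusted over the list alone, camera adjusted p = 0.00672, adjusted p = 0.0705 with an estimated correlation). Of 16 B-cell genes 14 fell, Cd74 by 5.26 ± 0.74 and Cd79b by 2.71 ± 0.23, and 1 rose (14 and 1 adjusted over the list alone, camera adjusted p = 0.000201, adjusted p = 0.0238 with an estimated correlation). Of 8 erythroid genes 5 fell and 1 rose, with a median of -6.65 (-5.34 with such genes at their bound, 5 and 1 adjusted over the list alone, camera adjusted p = 7.84e-07, adjusted p = 0.00114 with an estimated correlation). Hbb-bs averaged 85.8 ± 8.90 CPM and Hba-a1 68.4 ± 7.91 CPM in splenic cells, against 0.063 ± 0.0887 and 0.126 ± 0.192 CPM in iRTE, globin families in which reads can be shared. The changes were -9.98 for Hbb-bs and -8.87 for Hba-a1, or -10.76 and -10.42 without iRTE 4.

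Of 26 naive and quiescence genes 13 fell, Lef1 by 1.32 ± 0.19 and Satb1 by 0.88 ± 0.13, and 5 rose, Ccr4 by 4.56 ± 0.38 (13 and 6 adjusted over the list alone), and camera did not call the list (limma camera adjusted p = 0.236). The DP thymocyte list was not called either (9 rose and 9 fell, 9 and 10 adjusted over the list alone, limma camera adjusted p = 0.236), and its median of -0.02 (0.01 with such genes at their bound), mean of 0.20 and camera direction (lower) differed in sign, as did the median (0.53) and mean (-0.39) of the myeloid list. The positive selection, trafficking, immediate early, imprinted, stromal, thymic epithelial and myeloid lists were not called (limma camera adjusted p from 0.0709 to 0.793), and the imprinted and immediate early lists were called higher in iRTE 4 and 5 alone. On the latter iRTE 4 lay below every splenic library (list mean 4.75 against 5.41 to 5.63), so that call rested on iRTE 5.

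The third comparison put the monolayer product beside the same splenic cells. Rag1 averaged 153 ± 12.6 CPM, at least 748-fold above splenic cells, which had no count, Rag2 rose from 0.0216 ± 0.0483 to 59.1 ± 5.72 CPM and Cd24a from 3.65 ± 0.991 to 382 ± 23.2 CPM. Rag2 rose by 10.72 with all libraries and by 12.75 without splenic library 1, and Cd4 by 6.53 and by 9.02 without it. Cd8a fell by 0.98 ± 0.05, Cd8b1 by 1.13 ± 0.07, Ccr7 by 1.38 ± 0.06, Il7r by 1.77 ± 0.12, Ccr9 by 1.58 ± 0.05 and Cd69 by 3.75 ± 0.11. S1pr1 (-0.14 ± 0.06), Klf2 (-0.02 ± 0.09), Il2rb (-0.05 ± 0.06) and Cd44 (0.00 ± 0.38) did not pass, with edgeR adjusted p from 0.499 to 0.997. Gzmb rose by 4.46 ± 0.17, Tbx21 by 2.63 ± 0.18, Eomes by 2.44 ± 0.27, Pdcd1 by 5.18 ± 0.11 and Mki67 by 1.76 ± 0.18. Dntt rose by 0.87 ± 0.10 (edgeR adjusted p = 0.0437) and missed the threshold without any of the 5 splenic libraries or without OP9 CD8 1, 2, 4 or 5, where the change was 0.80 to 0.91, and with no filter. S1pr1 fell in a fit of these groups alone.

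The largest rises were Nov (at least 1589-fold), Rag1, Syt13 (at least 564-fold), Gnai1 (at least 459-fold), the Y-linked Ddx3y (at least 308-fold) and Prss57 (at least 281-fold), all with no count in splenic cells, and limma-voom did not call Ddx3y (10.85). Xlr3b was at least 200-fold, Cd86 at least 115-fold, Tdgf1 at least 113-fold and Aqp3 at least 69.9-fold lower, and Tmie changed by -10.13 ± 0.34 and Oas2 by -9.79 ± 0.33 (-13.06 and -10.58 without OP9 CD8 2). In all 4225 genes were higher and 4210 lower, of which 2381 and 2492 changed at least 2-fold. There was no overlap at 8502 genes (61.1%, chance 0.794%). Both groups were placed in set B, so by that assignment this comparison lay within a set.

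Camera called 22 of 27 lists in this comparison, 11 of them with an estimated correlation too. Of the 44 cell cycle genes all rose (44 adjusted over the list alone), Mcm5 from 79.3 ± 8.53 to 807 ± 36.6 CPM and E2f2 by 2.04 ± 0.07 (camera adjusted p = 2.51e-26, adjusted p = 0.0625 with an estimated correlation). Of 26 DP thymocyte genes 18 rose, Bcl2l1 by 2.39 ± 0.08 among them, and 6 fell (18 and 7 adjusted over the list alone, camera adjusted p = 0.00171, adjusted p = 0.0356 with an estimated correlation). Of 26 naive and quiescence genes 19 fell, Bach2 by 2.86 ± 0.13 and Ms4a6b by 1.30 ± 0.03, and 3 rose, Ccr4 by 4.30 ± 0.37 (19 and 3 adjusted over the list alone, camera adjusted p = 1.88e-05, adjusted p = 0.0625 with an estimated correlation). Of 40 interferon response genes 36 fell, Usp18 by 4.48 ± 0.14 and Samd9l by 3.28 ± 0.10, and 2 rose, Ifitm3 by 4.49 ± 0.20 (36 and 2 adjusted over the list alone, camera adjusted p = 4.46e-14, adjusted p = 0.0495 with an estimated correlation). Of 21 MHC class I genes 16 fell, H2-K1 by 2.82 ± 0.05 and H2-D1 by 2.14 ± 0.07, and 1 rose (16 and 2 adjusted over the list alone, camera adjusted p = 3.13e-12, adjusted p = 0.0471 with an estimated correlation). Of 28 receptor signalling genes 19 fell, Ubash3a by 1.94 ± 0.05 and Plcg1 by 1.73 ± 0.07, and 3 rose, Cd28 by 0.73 ± 0.09 (19 and 3 adjusted over the list alone, camera adjusted p = 2.37e-05, adjusted p = 0.0146 with an estimated correlation). Of 26 endoplasmic reticulum and amino acid stress genes 22 rose, Slc7a5 by 3.11 ± 0.07 and Asns from 0.0822 ± 0.115 to 215 ± 9.24 CPM, and 1 fell (22 and 1 adjusted over the list alone, camera adjusted p = 4.55e-13, adjusted p = 0.0309 with an estimated correlation). Asns rose by 11.25, or 12.31 without splenic library 4.

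Of 12 fetal programme genes 11 rose, Hmga1 by 2.85 ± 0.08 and Igf2bp3 by 4.22 ± 0.10, with a median of 3.53 (2.71 with such genes at their bound, 11 adjusted over the list alone, camera adjusted p = 2.26e-06, adjusted p = 0.0625 with an estimated correlation). Of 28 cytotoxic effector genes 17 rose, Lgals3 by 6.76 ± 0.46 (7.47 without splenic library 5) among them, and 4 fell, Ctsw by 2.49 ± 0.08 (18 and 4 adjusted over the list alone, camera adjusted p = 2.37e-05, adjusted p = 0.0625 with an estimated correlation). Of 12 gamma-delta T genes 9 rose, Tcrg-C2 by 5.08 ± 0.04 and Tcrg-C1 by 5.59 ± 0.08, related constant genes in which reads can be shared, and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 2.71e-13, adjusted p = 3.63e-05 with an estimated correlation). The glycolysis, hypoxia, p53 and apoptosis and CD4 helper lists were called higher and the erythroid list lower under both correlations. Oxidative phosphorylation, cholesterol synthesis, innate receptors, inhibitory receptors, imprinted genes and thymic epithelial genes were higher and B-cell genes lower with the preset correlation alone, with adjusted p = 0.0625 to 0.252 with an estimated correlation. The inhibitory receptor list had a median of -0.37 and a mean of 1.27, trafficking a median of -0.14 and a mean of 0.65, and positive selection a median of -0.18 with camera pointing higher. Positive selection, trafficking, immediate early, stromal and myeloid genes were not called.

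**Figure D2:**
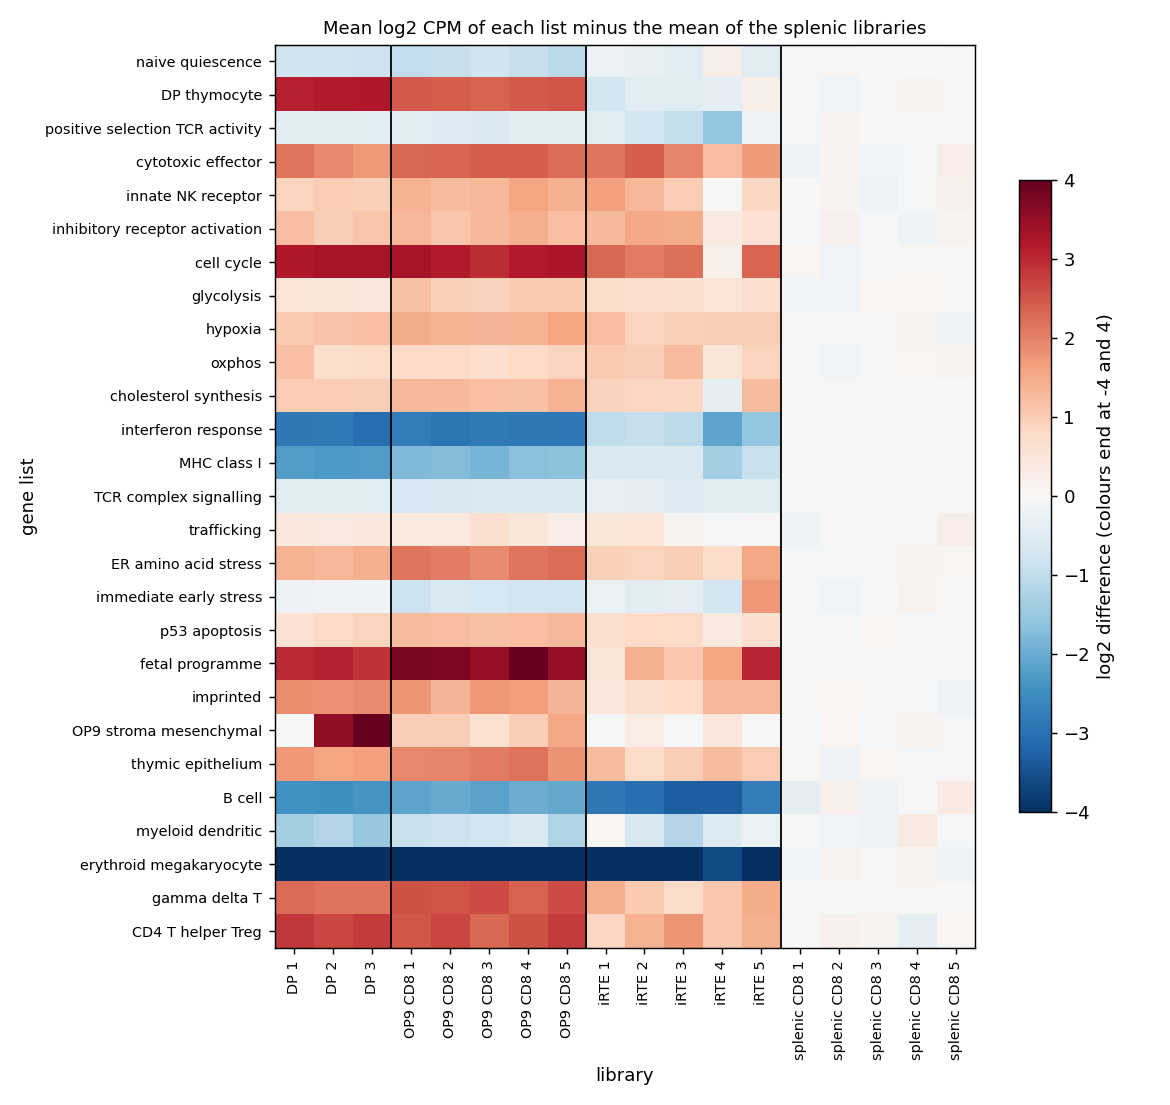
Mean log2 CPM of each gene list in each library minus the mean of the 5 splenic libraries, with lists as lines and libraries as columns. Interferon response and MHC class I genes were lowest in DP and OP9 CD8 libraries and closer to 0 in iRTE. Of the iRTE libraries, iRTE 4 was lowest on cell cycle genes.

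Changes from splenic cells were largely shared by both kinds of cultured cells. Rises in both comparisons covered 2939 genes where independent lists would share 1235, falls covered 2825 where 1219 were expected, and 292 genes were called in opposite directions, so that 95.2% of genes called in both moved the same way. Log2 changes correlated across genes at r = 0.733 with a covariance of 2.77. Because both comparisons used the same 5 splenic libraries, chance alone gives a correlation: groups simulated without any change gave r = 0.207 and a covariance of 0.0384 as a mean of 20 simulations. With the splenic libraries divided so that each comparison had its own controls, the median over 20 divisions was r = 0.706, with 2257.5 genes higher in both (825 expected) and 2194.5 lower in both (833 expected).

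The next measure asked which cultured group had a transcriptome nearer to the splenic one, as the root mean square log2 CPM difference from the splenic mean over the 13922 genes. The distance was 1.67 ± 0.064 (SD, n = 5) in iRTE, 1.71 ± 0.0338 (SD, n = 5) in OP9 CD8 and 1.76 ± 0.0382 in DP. The difference of -0.0413 between iRTE and OP9 CD8 did not pass an exact two-sided permutation test (p = 0.222). It depended on the libraries and the measure: it was -0.0649 without iRTE 3 (exact permutation p = 0.0317), -0.0238 without iRTE 4 and -0.0295 without iRTE 5 (exact permutation p = 0.429 and 0.381) and -0.0278 without OP9 CD8 5 (exact permutation p = 0.413). Within set B, iRTE 4 and 5 lay nearer to splenic cells than OP9 CD8 cells did (a difference of -0.1002, exact permutation p = 0.0476, the smallest that the arrangements can give). The difference was absent in iRTE 1 to 3 (-0.00212, exact permutation p = 0.982). As 1 minus Spearman correlation, a measure of rank order, the distance was 0.106 in iRTE and 0.130 in OP9 CD8 (exact two-sided permutation p = 0.00794, the smallest that the arrangements can give). It was 0.128 in DP, so the order of the OP9 CD8 and DP means turned with the measure.

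On the line from the DP mean (0) to the splenic mean (1), drawn over 4749 genes that differed at least 2-fold between these groups (2544 higher and 2205 lower in splenic cells), iRTE stood at 0.329 ± 0.0262 (SD, n = 5) and OP9 CD8 at 0.149 ± 0.0185 (SD, n = 5). Every iRTE library lay beyond every OP9 CD8 library (exact two-sided permutation p = 0.00794, the smallest that the arrangements can give). Within set B, iRTE 4 and 5 stood at 0.358 (exact permutation p = 0.0476, the smallest possible), and iRTE 1 to 3 stood at 0.311.

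**Figure D3:**
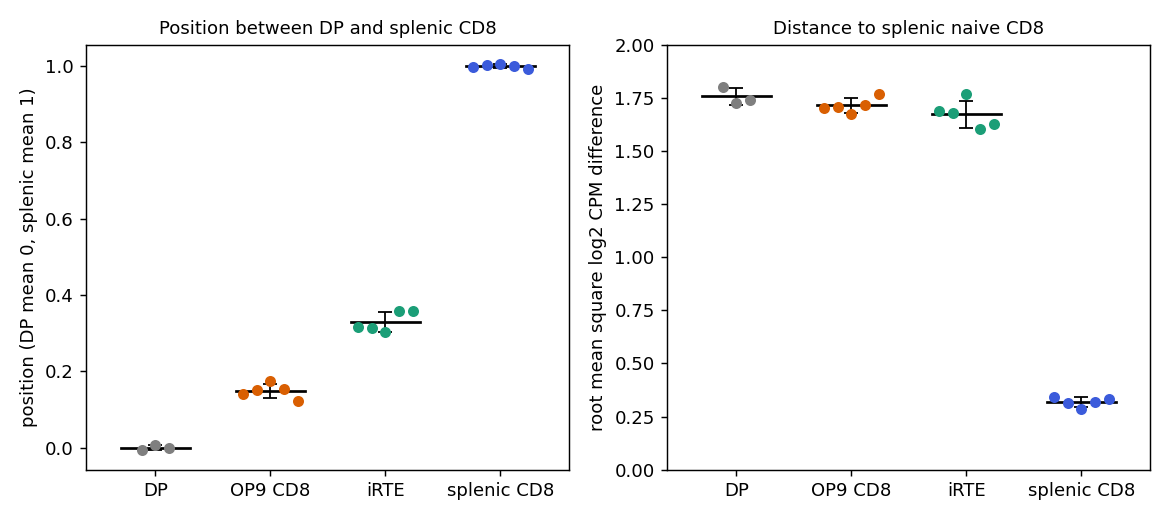
Position of each library between the DP mean and the splenic mean (left) and distance to the splenic mean in log2 CPM (right), with a point per library, a bar at the mean and error bars of 1 SD, where splenic libraries are measured against a mean that includes them. The iRTE mean position was 0.329 and the OP9 CD8 mean 0.149, and their distances, 1.67 and 1.71, overlapped.

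The fourth comparison asked what changed between CD4+CD8+ precursors and iRTE cells. Cd4 fell from 224 ± 59.9 CPM to no count in any iRTE library, at least 934-fold, but DP cells were selected as CD4+CD8+ and the other groups as CD8+, so the sort selected on CD4 in every comparison with DP. Rag1 fell from 389 ± 114 CPM (-9.04 ± 0.93), Rag2 from 147 ± 38.2 CPM (-8.29 ± 0.78), Dntt from 119 ± 10.4 CPM (-4.34 ± 0.64), Pdcd1 by 4.42 ± 0.34 and Cd24a by 3.16 ± 0.77. Without iRTE 5 the changes were -13.71 for Rag1 and -9.21 for Rag2, and without iRTE 4 they were -5.11 for Dntt and -3.89 for Cd24a. Cd8b1 rose by 0.85 ± 0.21, Il7r by 1.35 ± 0.25, S1pr1 by 0.81 ± 0.24, Ccr9 by 0.96 ± 0.13 and Ccr7 by 0.59 ± 0.20. Ccr7 was not past the threshold without DP 2 (0.52) or DP 3 (0.52). Cd69 was called higher with all libraries (3.77 ± 0.97) and without iRTE 5 (1.53), but not within set A (1.79), with a replicate block (2.25) or with limma-voom (2.28). Eomes fell by 1.51 ± 0.55, not without DP 2 (-1.36) or DP 3 (-1.48) or within set A (-1.17), and Mki67 fell by 1.94 ± 0.76 (by 2.69 without iRTE 5). In a fit of these groups alone Ccr7, S1pr1, Cd69, Eomes and Mki67 were not called. Cd8a did not pass (0.41 ± 0.33, edgeR adjusted p = 0.220) but rose by 0.61 without iRTE 4, and Klf2 did not pass (0.52 ± 0.30, edgeR adjusted p = 0.107) but rose by 0.68 without iRTE 5. Cd44, Il2rb, Gzmb and Tbx21 did not pass, with edgeR adjusted p from 0.175 to 0.908, and Cd44 (-3.51) and Tbx21 (-3.43) fell in iRTE 4 and 5 alone.

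The largest rises were Klhl14 (at least 113-fold), H2-Q6 (7.98 ± 0.94, or 9.31 without DP 2), Rgs1 (5.99 ± 0.86), Abhd14a (5.58 ± 1.17, or 6.58 without DP 1), H2-Q7 (5.52 ± 0.43) and Ifit3 (5.40 ± 0.92, not called with limma-voom, 4.38). H2-Q6 and H2-Q7 are close relatives, so which member rose is uncertain. Next to Cd4, large falls were those of Arhgef10l (at least 126-fold), F13a1 (at least 99.7-fold), Esrp1 (at least 78.8-fold) and Slc5a9 (at least 77.6-fold). In all 1648 genes were higher and 1719 lower, of which 746 and 936 changed at least 2-fold. There was no overlap at 2715 genes (19.5%, chance 3.57%). Within set A, iRTE 1 to 3 were higher than DP at 1834 genes and lower at 2094. In a fit of these groups alone 516 were higher and 552 lower.

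Camera called 10 lists, 2 of them with an estimated correlation. Of 26 DP thymocyte genes 20 fell, Ets2 (-3.15 ± 0.16) among them, and 2 rose (21 and 2 adjusted over the list alone, camera adjusted p = 6.84e-32, adjusted p = 1.3e-07 with an estimated correlation). Of 21 MHC class I genes 19 rose, H2-K1 by 2.01 ± 0.07 and H2-D1 by 1.82 ± 0.10, and 1 fell (19 and 1 adjusted over the list alone, camera adjusted p = 4.99e-25, adjusted p = 0.0221 with an estimated correlation). Of 40 interferon response genes 34 rose, Ifi47 by 2.28 ± 0.24 and Oasl2 by 2.85 ± 0.28 (34 and 1 fell adjusted over the list alone, camera adjusted p = 3.46e-19, adjusted p = 0.0771 with an estimated correlation). Of 44 cell cycle genes 34 fell, E2f2 by 1.21 ± 0.19 and E2f8 by 1.96 ± 0.32, and E2f1 rose by 0.72 ± 0.23 (40 and 1 adjusted over the list alone, camera adjusted p = 1.3e-16, adjusted p = 0.251 with an estimated correlation), with a median of -1.16 in iRTE 1 to 3 and -1.82 in iRTE 4 and 5. The call of E2f1 was lost without DP 1 (0.68), DP 3 (0.65) or iRTE 3 (0.58), with a replicate block (0.72) and in a fit of these groups alone (0.72). Of 26 naive and quiescence genes 11 rose, Ly6c2 by 4.66 ± 0.39 and Igfbp4 by 3.47 ± 0.31, and 4 fell, Satb1 by 0.92 ± 0.13 (14 and 4 adjusted over the list alone, camera adjusted p = 4.84e-05, adjusted p = 0.169 with an estimated correlation). Of 14 stromal genes 10 fell, Cxcl12 at least 31.1-fold and Col1a2 by 8.34 ± 2.14, with a median of -5.80 (-3.52 with such genes at their bound, 10 adjusted over the list alone, camera adjusted p = 0.0341, adjusted p = 0.460 with an estimated correlation). Within set A the stromal list was not called, with 7 members lower, nor was it without iRTE 5. DP 1 had no count of Col1a2, limma-voom did not call it (-5.25), and its fitted change was -8.93 without DP 1 and -9.80 without iRTE 4, and that of Cxcl12 moved from -9.78 to -10.37 without DP 1 and -8.02 without DP 3.

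Glycolysis (10 rose and 2 fell of 22, 12 and 2 adjusted over the list alone, camera adjusted p = 0.0044, adjusted p = 0.169 with an estimated correlation) and trafficking (9 and 5 of 23, 12 and 5 adjusted over the list alone, camera adjusted p = 0.0157, adjusted p = 0.158 with an estimated correlation) were higher. The trafficking list had a median of 0.59 and a mean of -0.13. Fetal programme genes (4 fell of 12, 4 adjusted over the list alone, camera adjusted p = 0.00345, adjusted p = 0.290 with an estimated correlation) and gamma-delta T genes (3 rose and 4 fell of 12, 4 and 4 adjusted over the list alone, camera adjusted p = 0.0467, adjusted p = 0.158 with an estimated correlation) were lower, the latter with a median of 0.13 and a mean of -1.06. The gamma-delta call was lost within set A and without iRTE 5 or DP 1, and the glycolysis and fetal programme calls were lost in iRTE 4 and 5 alone. The other 17 lists were not called. Of those, positive selection (median -0.04, mean 0.25), hypoxia (median 0.10, mean -0.02), p53 and apoptosis (median -0.06, mean 0.00277) and endoplasmic reticulum and amino acid stress (median 0.07, mean -0.48) differed in sign, and the immediate early list was called higher in iRTE 4 and 5 alone, again resting on iRTE 5 (7.23, iRTE 4 at 4.75). Regrouped libraries gave up to 13 list calls where these groups gave 10 in a fit of their own.

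The fifth comparison asked how OP9 CD8 cells differed from the DP cells of the same culture system. These groups lie in different label sets, so culture stage and set cannot be told apart without the bridging iRTE libraries. Cd4 fell from 224 ± 59.9 to 4.41 ± 2.85 CPM, while Rag1 averaged 389 ± 114 CPM in DP and 153 ± 12.6 CPM in OP9 CD8. Rag1 did not pass (-1.35 ± 0.28, edgeR adjusted p = 0.0873, and fell in a fit of these groups alone), and Rag2 fell by 1.31 ± 0.25, not without DP 2 (-1.20), DP 3 (-1.20), OP9 CD8 2 (-1.29) or OP9 CD8 4 (-1.28), nor with DESeq2. Cd8b1 fell by 0.61 ± 0.18, not without DP 1 (-0.43). Ccr9 fell by 0.37 ± 0.07 (edgeR adjusted p = 0.0423), not past the threshold under other scalings or without any of the DP libraries or OP9 CD8 1, 2, 4 or 5. Pdcd1 rose by 1.14 ± 0.08. Of the other key genes Cd8a (-0.58 ± 0.11), Dntt (-0.72 ± 0.12), Ccr7 (-0.21 ± 0.14), S1pr1 (-0.15 ± 0.06), Klf2 (-0.23 ± 0.17), Il7r (0.28 ± 0.12), Cd24a (1.54 ± 0.12) and Il2rb (0.49 ± 0.11) did not pass. Neither did Cd69 (-0.30 ± 0.18), Cd44 (0.19 ± 0.31), Gzmb (-0.95 ± 0.16), Tbx21 (1.55 ± 0.25), Eomes (0.22 ± 0.24) and Mki67 (-1.02 ± 0.16), with edgeR adjusted p of these 14 genes from 0.0533 to 0.914. In a fit of these groups alone Cd8a, Dntt, Cd24a, Il2rb, Gzmb, Tbx21 and Mki67 were called, in the same directions, as were Rag1, Dntt and Cd24a with limma-voom and Cd24a with DESeq2, upper quartile scaling or the 10 CPM filter. With a label set term Rag1 (-6.65), Ccr7 (-0.68) and Cd69 (-3.36) were called lower and Il7r (0.94), Cd44 (4.61) and Tbx21 (5.33) higher. These shifts came through iRTE, those of Rag1 and Cd69 through iRTE 5 (3.07 CPM of Rag1). Cd4, Ldoc1l and Evc, with no count in iRTE, were not called. That term kept 919 of the calls (45.0%).

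Smpdl3a was at least 92.8-fold, Ldoc1l at least 59.7-fold and Evc at least 54.3-fold higher, with no count in DP. BC064078 changed by -6.56 ± 0.57 (-8.39 without OP9 CD8 5) and the Y-linked Kdm5d by -5.94 ± 0.97 (-9.15 without OP9 CD8 2). The call of Kdm5d was lost without DP 2, DP 3 or OP9 CD8 1, 3, 4 or 5 (-5.62 to -5.78) and with no filter. In all 910 genes were higher and 1131 lower, of which 506 and 325 changed at least 2-fold. The groups did not overlap at 4035 genes (29.0%, chance 3.57%). The number higher was 522 without DP 1, 594 without DP 2 and 586 without DP 3. A fit of these groups alone gave 1650 higher and 1712 lower.

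Camera called 8 lists. Of 26 DP thymocyte genes 11 fell, Cd4 and Ets2 (-2.51 ± 0.10) among them, and 15 did not pass (14 fell and 1 rose adjusted over the list alone, camera adjusted p = 4.86e-08, adjusted p = 0.00227 with an estimated correlation). Of 26 endoplasmic reticulum and amino acid stress genes 14 rose, Slc7a5 by 1.33 ± 0.07 and Hyou1 by 1.30 ± 0.37, and 2 fell (17 and 2 adjusted over the list alone, camera adjusted p = 7.06e-10, adjusted p = 0.0908 with an estimated correlation). Of 22 glycolysis genes 7 rose, Slc16a1 by 0.99 ± 0.10 and Pkm by 0.76 ± 0.08 (10 adjusted over the list alone, camera adjusted p = 0.000186, adjusted p = 0.0908 with an estimated correlation). Of 21 MHC class I genes 8 rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.000767, adjusted p = 0.632 with an estimated correlation). Of 24 p53 and apoptosis genes 8 rose and 3 fell (11 and 5 adjusted over the list alone, camera adjusted p = 0.0381, adjusted p = 0.0908 with an estimated correlation). Among 12 fetal programme genes 2 rose (4 adjusted over the list alone, camera adjusted p = 0.0442, adjusted p = 0.632 with an estimated correlation). Of 28 receptor signalling genes 7 fell (7 adjusted over the list alone, camera adjusted p = 0.0155, adjusted p = 0.109 with an estimated correlation). Of 20 immediate early genes 2 fell (1 adjusted over the list alone, camera adjusted p = 0.0442, adjusted p = 0.648 with an estimated correlation). The other 19 lists were not called. Among them positive selection (median -0.10, mean 0.02), trafficking (mean 0.01, lower by camera), CD4 helper (median 0.62, mean -0.17) and gamma-delta T genes (median -0.03, mean 0.30) differed in sign. Regrouped libraries gave up to 12 list calls where these groups gave 11 in a fit of their own, and with a label set term the cell cycle and oxidative phosphorylation lists were called higher (limma camera adjusted p = 0.000137 and 0.00786). That term also added calls of the cytotoxic effector, inhibitory receptor, cholesterol synthesis, interferon response and CD4 helper lists and ended those of receptor signalling and the fetal programme. Without DP 1 the p53 and fetal programme calls were lost.

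The sixth comparison set the ends of the series, DP and splenic naive cells, against each other, again across label sets. Cd4 changed by -12.18 ± 0.33 (-14.66 without splenic library 1) and Rag2 by -12.03 ± 0.29 (-14.06 without it). Rag1 was at least 1903-fold, Nov at least 1185-fold and Ptcra, the pre-T-cell receptor chain, at least 628-fold lower, and Cd24a fell by 5.17 ± 0.20. Ccr7 rose by 1.18 ± 0.14, Il7r by 2.05 ± 0.06, Ccr9 by 1.21 ± 0.06, Cd69 by 3.45 ± 0.15, Il2rb by 0.53 ± 0.10 (not without DP 1, 0.44) and Cd8b1 by 0.51 ± 0.17 (not without DP 2 or DP 3, 0.42 each). Dntt fell by 1.60 ± 0.07, Gzmb by 5.41 ± 0.10, Eomes by 2.22 ± 0.28, Pdcd1 by 4.05 ± 0.13 and Mki67 by 2.78 ± 0.24. Cd8a (0.40 ± 0.11), S1pr1 (-0.01 ± 0.03), Klf2 (-0.21 ± 0.15), Cd44 (0.19 ± 0.47) and Tbx21 (-1.08 ± 0.27) did not pass, with edgeR adjusted p from 0.142 to 0.968. Smpdl3a was at least 434-fold, Xist at least 384-fold and Hbb-bs at least 342-fold higher in splenic cells. In all 3809 genes were higher and 4019 lower, of which 2544 and 2205 changed at least 2-fold. There was no overlap at 8823 genes (63.4%, chance 3.57%). With a label set term, again through iRTE, 2019 were higher and 2496 lower, and 3884 calls (49.6%) were kept. Under that term Cd69 (0.38), Il2rb (0.77), Cd8b1 (0.18), Eomes (-1.20), Cd4, Xist and Hbb-bs were not called, and Cd8a (0.97), Cd44 (4.60) and Tbx21 (2.69) were called higher. A fit of these groups alone called Cd8a higher and Tbx21 lower.

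Of the 44 cell cycle genes all fell in splenic cells (44 adjusted over the list alone), E2f2 by 2.52 ± 0.16 and Ccnb1 from 264 ± 19.2 to 6.86 ± 0.516 CPM (camera adjusted p = 2.94e-30, adjusted p = 0.0687 with an estimated correlation). Of 40 interferon response genes 36 rose, Usp18 by 4.34 ± 0.18 and Rtp4 by 2.94 ± 0.21, and 1 fell (36 and 1 adjusted over the list alone, camera adjusted p = 9.09e-15, adjusted p = 0.0523 with an estimated correlation). Of 21 MHC class I genes 16 rose, H2-K1 from 500 ± 17.5 to 4995 ± 232 CPM and Nlrc5 by 3.70 ± 0.14, and 1 fell (16 and 1 adjusted over the list alone, camera adjusted p = 2.07e-15, adjusted p = 0.0384 with an estimated correlation). Of 27 lists 21 were called, and 6 of these held with an estimated correlation: MHC class I (higher), DP thymocyte, imprinted, gamma-delta T and CD4 helper genes (lower) and erythroid genes (higher). Naive, receptor signalling and B-cell genes were higher and cytotoxic, innate and inhibitory receptor, glycolysis, hypoxia, oxidative phosphorylation, cholesterol synthesis, stress, p53 and fetal programme genes lower with the preset correlation alone, with adjusted p = 0.0523 to 0.198 with an estimated correlation. The inhibitory receptor list had a median of 0.39 and a mean of -0.94, trafficking a median of 0.19 and a mean of -0.64, and positive selection a median of 0.34 with camera pointing lower. With a label set term the innate and inhibitory receptor, glycolysis, hypoxia, p53, B-cell and erythroid lists were not called.

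**Figure D4:**
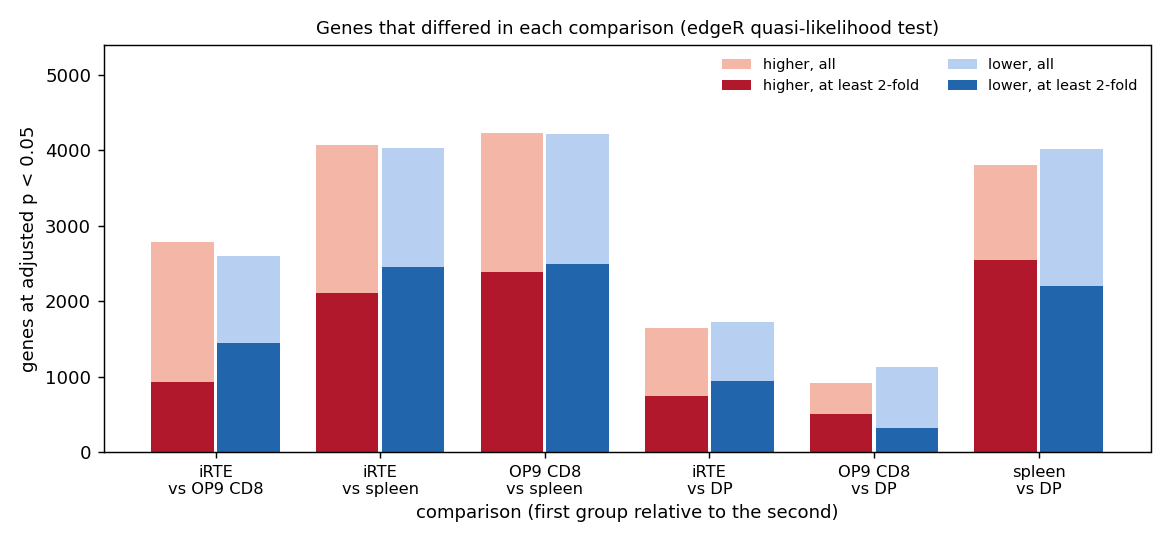
Number of genes higher and lower in the first group of each comparison at an adjusted p under 0.05 in the edgeR test, with the darker part of each bar counting genes changed at least 2-fold. Counts ran from 910 higher and 1131 lower between OP9 CD8 and DP to 4225 higher and 4210 lower between OP9 CD8 and splenic cells.

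The iRTE libraries also differed among themselves by label set. Between iRTE 1 to 3 and iRTE 4 and 5, 902 genes were higher and 1018 lower, 1920 in all. The total was 3133 without iRTE 5 and 1548 without iRTE 3. Interferon response genes were higher in iRTE 1 to 3 (19 of 40 rose and 2 fell, limma camera adjusted p = 1.48e-14), as were MHC class I genes (9 of 21 rose, limma camera adjusted p = 4.3e-07), and immediate early genes were lower (11 of 20 fell and 1 rose, limma camera adjusted p = 0.000307). The last rested on iRTE 5, at a list mean of 7.23, since iRTE 4 held the lowest of the 5 (4.75). Camera also called the oxidative phosphorylation, cytotoxic effector, inhibitory and innate receptor lists higher and the fetal programme and DP thymocyte lists lower in iRTE 1 to 3, and the cell cycle list higher, which rested on iRTE 4 (4.19), since iRTE 5 lay with iRTE 1 to 3 (6.07 to 6.31). The share of mitochondrial counts split the same way, at 1.76 to 2.17% in iRTE 1 to 3 and 0.868 to 0.903% in iRTE 4 and 5. These 5 libraries carry both the set and whatever differed between cultures, which this design does not separate.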

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

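Single libraries that stood apart from their group were sought with Dixon's test in groups of 5 libraries, and the tests of explanations in the last 4 paragraphs below, other than the regroupings, were chosen after the results were seen. Of 420 groups tested 45 held such a library (10.7%), where chance gives about 1 in 20: 39 of 335 for genes (11.6%) and 6 of 81 for lists (7.41%). Of these, 12 genes and 2 lists stood apart in iRTE 4, and 9 genes and 2 lists in iRTE 5.

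Library iRTE 4 was low in genes of division. Its mean log2 CPM was 4.19 over the cell cycle list (other iRTE 6.07 to 6.31) and 4.29 over cholesterol synthesis (others 5.48 to 5.90). Mcm5 stood at 132 CPM (others 279 to 368), Mcm2 at 162 CPM and Ccnb1 at 10.9 CPM (others 61.9 to 88.7). Cd8a was low at 456 CPM (others 1262 to 1385), as were Gzmb at 6.85, Ctsw at 177, H2-D1 at 2823, Osgin1 at 4.30 and Abhd14a at 1.43 CPM, and Cd86 was at 0. Ccr7 was high at 998 CPM (others 563 to 662), and so was Aqp3 at 6.67 CPM, which had no count in the other iRTE libraries.

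Library iRTE 5 was high in immediate early genes, with a list mean of 7.23 against 4.75 to 5.22 in the other iRTE libraries, and in stress genes of the endoplasmic reticulum (5.92, others 5.12 to 5.35). Klf6 stood at 540 CPM (others 326 to 370), Ddit3 at 27.7 CPM and Cd28 at 42.2 CPM. Traces of thymocyte transcripts were seen in it: Rag1 at 3.07 CPM and Ptcra at 4.16 CPM. Il7r (125 CPM), Ccl5 (27.6 CPM) and BC064078 (0.896 CPM) were low, and Ddx3y was at 0 (others 43.4 to 111).

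Among the other libraries, iRTE 1 was high on the hypoxia list (4.78, others 4.43 to 4.52) and low in Sox4 (1.82 CPM), and iRTE 3 was low in Tcrg-C2 (789 CPM). In OP9 CD8 cells, library 3 stood apart at Ccr9 (315 CPM), Xbp1 (272 CPM), Sox4 (105 CPM) and Ets2 (35.5 CPM), library 5 at Cd8a (644 CPM) and Cd28 (52.0 CPM), library 4 at Rtp1 (19.96 CPM), library 1 at Cd69 (24.4 CPM) and library 2 at Kdm5d (3.39 CPM). In splenic cells, library 2 stood apart on the positive selection list (5.93, others 5.78 to 5.80) and at Osgin1 (3.68 CPM), Mki67 (18.8 CPM) and Tcf7 (1401 CPM). Splenic library 5 stood apart at Klf6 (224 CPM), Ifitm1 (1.44 CPM) and Ly6e (866 CPM), and library 4 at Mcm2 (108 CPM).

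In 13 named genes iRTE and OP9 CD8 cells differed from splenic cells in opposite directions. The edgeR comparison of iRTE with OP9 CD8 on these libraries called each, which after that selection is no test. Higher in iRTE were Rgs1 (6.14), Osgin1 (5.19), Jun (4.48), Cxcr6 (3.64), Slfn2 (1.93), Cd8b1 (1.47) and Klf6 (1.38). Lower, as fitted values, were Evc (-10.65), F13a1 (-8.9995), Tmem151b (-8.73), Arhgef10l (-7.37), Dntt (-3.62) and Sox4 (-3.34). Evc, F13a1 and Arhgef10l had no count in iRTE, so their fitted values depend on the prior count, and the counts show at least 56.9-fold, 18.2-fold and 5.81-fold lower values. Against splenic cells the calls of Cd8b1 in iRTE and Dntt in OP9 CD8 were lost without single libraries.

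The rise of immediate early genes in iRTE over OP9 CD8 was not carried by iRTE 5 alone: without that library 9 of 19 members were called higher and 4 lower, with a median of 0.52 (1.25 with it) and a limma camera adjusted p of 0.0108. With an estimated correlation the list was not called even with all libraries (limma camera adjusted p = 0.348). The label sets cannot be told apart from the groups here. Within set B the list was higher in iRTE 4 and 5 (limma camera adjusted p = 2.07e-07), but this rests on iRTE 5: iRTE 4 had a list mean of 4.75, inside the OP9 CD8 range of 4.64 to 4.89. So iRTE 5 and the sets together stay open as the cause. The handling of the cells was not measured, and these genes answer to it, so handling stays open next to the culture, which is untested. Fos (147 CPM) and Egr1 (356 CPM), chosen after their values were seen, were far higher in iRTE 5 than in the other iRTE libraries (0.436 to 1.72 and 5.17 to 20.03 CPM).

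Interferon response and MHC class I genes were higher in iRTE than in OP9 CD8 cells within label set B as well (larger limma camera adjusted p of these lists, 2.08e-08), with both libraries above every OP9 CD8 library in list mean, which argues against the label sets as the whole cause. With all libraries and an estimated correlation neither list was called (limma camera adjusted p = 0.0896 each). Whether myeloid or dendritic cells among the iRTE cells add to it cannot be told apart: the 9 measured members of that list had a median log2 change of 0.17 with a median absolute deviation of 1.53, too wide to set against the class I median of 1.04. Its most abundant gene, Cst3, averaged 97.1 ± 24.1 CPM (SD) in iRTE and 91.3 ± 5.95 CPM in OP9 CD8, and the sort gate removed CD11c+ cells. The culture stays untested as a cause.

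Gamma chain constant genes of the T-cell receptor were higher in iRTE and OP9 CD8 than in splenic cells. Reads shared between these genes do not account for it. Their summed CPM was 2111 ± 332 (SD) in iRTE, 19.5 times the splenic 108 ± 5.87 CPM. The ratio was 23.3 in OP9 CD8 and 17.7 in DP. Gamma-delta T cells in the sort cannot be told apart. The 7 other members used had a median change of -1.14 in iRTE (median absolute deviation 5.24, only 3 at 10 CPM or more). In OP9 CD8 it was 2.28 (deviation 2.90), against medians of 4.88 and 5.34 for the 4 constant genes. A member that rose in both, of 12 measured, was left out. The sort gate removed cells with the gamma-delta receptor. Transcription of these genes in cultured alpha-beta cells stays open, untested.

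Other groupings of the same libraries into groups of the same sizes were tried in fits of the 2 groups alone. For gene counts 1 grouping, the real one, was as large in each comparison among those run. The count was 3921 genes against at most 1 in another grouping for iRTE and OP9 CD8. It was 6947 against 0 for iRTE and splenic cells and 9718 against 0 for OP9 CD8 and splenic cells. It was 3362 against 0 for OP9 CD8 and DP, and 9021 against 0 for splenic cells and DP. For iRTE and DP it was 1068 against 126, where the 126 came from DP with iRTE 4 and 5 against iRTE 1 to 3, a grouping that follows the iRTE label sets. For list counts chance can be excluded for iRTE and OP9 CD8 (15 against 12), iRTE and splenic cells (17 against 16), OP9 CD8 and splenic cells (22 against 21) and splenic cells and DP (22 against 20). It cannot for iRTE and DP (10 against 13, with 7 of 56 groupings as large) or OP9 CD8 and DP (11 against 12, with 5 of 56 as large).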

How the results depend on the processing

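Tests with iRTE 1 to 3 or iRTE 4 and 5 alone (other than the distance and position of iRTE 4 and 5), lists without iRTE 5 or DP 1, and library weights were chosen after the results were seen, and the other alternatives were planned. At a 2-fold threshold the genes higher and lower were 934 and 1443 (iRTE against OP9 CD8), 2106 and 2454 (iRTE against splenic cells), 2381 and 2492 (OP9 CD8 against splenic cells), 746 and 936 (iRTE against DP), 506 and 325 (OP9 CD8 against DP), and 2205 lower (splenic cells against DP). A fit of only the 2 groups gave 516 and 552 for iRTE against DP and 1650 and 1712 for OP9 CD8 against DP. Library weights gave 2816 lower for iRTE against DP, and 2298 and 2565 for OP9 CD8 against DP. A label set term gave 2019 and 2496 for splenic cells against DP and 13 lists for OP9 CD8 against DP. With an estimated correlation camera called 1, 6, 11, 2, 1 and 6 lists in the comparisons in the order above. The distance difference was -0.0233 as 1 minus Spearman correlation and -0.1002 with only iRTE 4 and 5.

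Leaving out each library in turn gave 2449 to 3008 genes higher and 2258 to 3002 lower for iRTE against OP9 CD8, 3873 to 4209 and 3606 to 4277 for iRTE against splenic cells, and 4001 to 4150 and 3804 to 3971 for OP9 CD8 against splenic cells. It gave 1115 to 1931 and 1293 to 2158 for iRTE against DP, 522 to 817 and 788 to 956 for OP9 CD8 against DP, and 3192 to 3476 and 3675 to 3937 for splenic cells against DP. Without iRTE 5, 13 lists were called for iRTE against OP9 CD8, 19 against splenic cells and 8 against DP. Without DP 1 they were 10 for iRTE, 7 for OP9 CD8 and 22 for splenic cells, each against DP. The distance difference ran from -0.0649 to -0.0238, the position difference from 0.174 to 0.187 and the genes differing between the iRTE sets from 1548 to 3133.

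Values called in either setting that changed direction were these, and the cause was not tested. Another 63 of 5540 gene values changed sign with a call in neither. For Cd69 in iRTE against splenic cells: -1.40 with library weights, -1.66 with iRTE 1 to 3 and, leaving out 1 library, -1.92 (without iRTE 5) to 0.62 (without iRTE 4). For Rag2, -2.04 with iRTE 1 to 3. Cd44 was at -3.70 against splenic cells with a label set term or iRTE 4 and 5, and at -3.51 against DP with iRTE 4 and 5. Tbx21 was at -2.35 against splenic cells with either, and splenic cells stood at 2.69 against DP with the term. With that term the limma camera adjusted p of lists that turned was 0.000137 (cell cycle), 0.00786 (oxidative phosphorylation) and 0.166 (fetal programme) for OP9 CD8 against DP and 0.807 (erythroid) for splenic cells against DP.

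With a replicate block the genes higher and lower were 2520 and 2624, 3827 and 4131, 4145 and 4205, 1394 and 1604, 826 and 995, and 3579 and 3747 in the 6 comparisons, with 10, 18, 22, 8, 7 and 21 lists. The groups share only the numbers, which is no pairing, and this block weakened 2 gene calls and 7 list calls and added 1 of each.

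The 273 gene results cover genes named in part for large changes. Scaling by RLE or upper quartile kept the call of 271 each, no filter 269 and limma-voom 262. The 10 CPM filter and DESeq2 each lost 1 call and gained 2. Leaving out a library kept the call of 2469 values, with 41 lost and 11 gained, and the label set term lost 14 and gained 10. For 162 list results the estimated correlation lost 65 calls, and fry lost 2 and gained 28.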

Other observations

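The genes and sums in this part and the distance of iRTE 1 to 3 were chosen after the results were seen, and the distance of iRTE 4 and 5 was planned. Itgae, the alpha chain that binds E-cadherin, averaged 1227 ± 422 CPM (SD, n = 5) in iRTE, 375 ± 29.4 CPM in OP9 CD8 and 745 ± 44.7 CPM in splenic cells, but iRTE 5, at 596 CPM, lay below every splenic library (687 to 803 CPM).

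Nov was high in all cultured groups and without a count in splenic cells, and within iRTE it followed the label sets: 1031 to 1091 CPM in iRTE 1 to 3, and 158 and 214 CPM in iRTE 4 and 5.

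Genes of the sex chromosomes told the cultured cells from the splenic ones. Xist stood at 76.1 to 115 CPM in splenic libraries, at 0.877 to 3.21 CPM in OP9 CD8 and at 0 in DP, while Eif2s3y and Uty were seen in every cultured library and had no count in splenic ones. This is the pattern of female splenic cells and a male cultured line. The labels used here give no sex, and by this measure sex and origin go together in every comparison with the spleen.

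Transcripts of other cells were summed over marker lists in CPM without TMM scaling. The erythroid sum was 216 ± 23.2 CPM in splenic cells, led by Hbb-bs, and 40.1 to 66.0 CPM in cultured groups, led by Gata1. Stromal genes summed to 259 CPM in DP, 205 CPM in iRTE, 172 CPM in OP9 CD8 and 55.9 CPM in splenic cells, led in each by Thy1, which T cells also express.

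The share of mitochondrial counts averaged 0.755% in splenic cells and 1.74% in OP9 CD8. It follows the label sets within iRTE but not between groups, since OP9 CD8 was placed in the same set as iRTE 4 and 5. The distance difference from OP9 CD8 was -0.1002 for iRTE 4 and 5, all within set B, and -0.00212 for iRTE 1 to 3, and why these differ was not tested.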
